A study of Mus musculus with 12 samples.

How the data were processed

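The gene table deposited by the authors was used as the starting point: it holds a whole read count and an FPKM value for each of 21899 genes in 12 libraries. The count and FPKM columns from the deposited table were checked against each other: count divided by gene length and library total gave the FPKM value for 184877 of 184877 values above 0, within a relative tolerance of 1e-05. Counts were used for every test, and FPKM only for that check. No column of values was left unused. Reads were not aligned again, so alignment and counting are the authors' and only as stated in their notes. According to those notes, reads were trimmed with cutadapt, aligned with TopHat2 or HISAT2, counted with HTSeq 0.9.1 and tested with DESeq 1.30.0 on build GRCm39. According to the protocol in the labels, reads were aligned to mm9 with HISAT2 2.0.5, so the build is stated in 2 ways. Of 21782 nuclear genes matched to a GRCm38 annotation by identifier, 501 share their start, and coordinates are therefore given only as the table holds them. Of 21795 matched genes, 21756 are protein coding. The strand setting of counting is not stated, which leaves genes overlapped on the opposite strand, such as mt-Nd6 with mt-Nd5, uncertain. How reads shared by near-identical copies (Hspa1a and Hspa1b, Tgtp1 and Tgtp2, copies of Cwc22, S100 and Stfa genes, Ly6c2) were counted is not stated either.

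Groups were taken from the sample titles, since the treatment label of the swimming libraries gives only corn oil and swimming stands in the title and protocol. Per the labels, curcumin was given each afternoon in 200 µL of corn oil and swimming followed gavage by 30 min. Library totals ran from 15069348 counts (curcumin 2) to 17278826 (control 2). A floor of 3 counts in a library, about the smallest expected count for which absence is unlikely from counting alone, stood at 0.174 to 0.199 CPM. Folds against a group with 0 counts set that group at 3 summed counts. For genes with hardly any counts in a group, exact conditional intervals on summed counts replaced fitted fold changes, and these intervals and floors cover counting error only.

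Genes were kept by filterByExpr (minimum count 10, minimum total 15), leaving 13638. Counts were scaled by TMM and fitted in edgeR 4.0.16 under R 4.3.3 with quasi-likelihood F-tests on all 12 libraries, which left 8 residual degrees of freedom. The 9 contrasts were each treatment against control, the combination against each single treatment, the interaction, each treatment averaged over the other, and the difference between single treatments. They were fixed before the data were examined, as were 42 lists of genes for pathways, cell types and RNA quality with 746 entries, of which 729 are in the table. The RNA quality lists hold mitochondrially encoded and ribosomal protein genes. The 38 lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, from limma 3.58.1. For all 135 list calls at the preset correlation, the adjusted p was larger with an estimated correlation. Called genes were counted over all genes and also after adjustment over the list's own members. Gene Ontology terms of 10 to 500 genes were tested on called genes, higher and lower apart, against all annotated tested genes. That hypergeometric test treats genes as independent, so its p-values can be too small where the genes of a term vary together.

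Named genes followed a fixed rule. For the 3 comparisons with control, called genes with ordinary symbols, at least 1 CPM in the higher group and no overlap between the 3 and 3 libraries gave the 10 largest changes per direction. Where fewer passed, all were taken with the 5 of smallest p. Other comparisons took 5 per direction, and each list past camera or with at least 3 called members gave its 4 members of smallest p. A panel of 10 tumour genes was read in every comparison. Log2 CPM used a prior count of 2, and list levels are means of centred log2 CPM over members.

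The pipeline was tested on simulated data with 200 changed genes among 13498. At 1.5, 2 and 4-fold it recovered 31.3%, 58.2% and 81.8% in curcumin against control, 34.3%, 64.2% and 80.3% in swimming against control and 41.8%, 70.1% and 95.5% in combination against control. False calls numbered 10, 12 and 11. In the simulation each gene had a single mean and a single dispersion over all libraries, apart from the planted changes. The real groups differed in spread, with a biological coefficient of variation from 6.43% (combination) to 23.5% (control). Recovery therefore does not measure the power of the real comparisons.

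Alternatives were DESeq2 1.42.0, RLE scaling, no filter, a mean count of at least 50, a fit of only the groups compared, replicate number as a block, a test against a 1.5-fold change and leaving out each library. After the results were seen, 3 more were added: combination libraries summed, the same without control 2, and limma voom with a weight per group. Tumour volume and body weight were not analysed here, and the saline group without tumour was not used here.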

Results

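Combined swimming and curcumin were compared with either measure alone in 4T1-LUC mammary tumours grown in BALB/c mice, using 12 RNA sequencing libraries in 4 groups of 3. The groups were tumour control (corn oil by gavage), curcumin (100 mg/kg in corn oil), swimming (corn oil with 30 min of swimming) and combination (curcumin with swimming). Libraries are named by group and replicate, such as control 2. Expression is in CPM (counts scaled to library size), given as mean ± SD with n = 3 per group, and log2 fold changes carry their standard error. Adjusted p-values are Benjamini-Hochberg values from edgeR over 13638 genes, and a gene was called at adjusted p of 0.05 or below. The labels do not state whether the libraries came from separate tumours or animals, so p-values measure only the spread between these samples.

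Marker lists set several libraries apart before any gene was tested. Control 2 had the lowest skeletal muscle level (-2.958, against 0.688 and 1.898 in controls 1 and 3), the lowest cell cycle level (-1.1, against 0.116 and -0.013) and the highest neutrophil level (1.386). Its expression correlated at 0.9778 with the swimming mean and at 0.9611 with the mean of its own group, and 4 other libraries lay closer to another group. Controls 1 and 3 correlated best with the curcumin mean (0.9863 and 0.9878, against 0.9759 and 0.9813 for their own), and swimming 2 and 3 with the control mean (0.98 and 0.9826, against 0.979 and 0.9809). Own-group means left out the library itself, so they rest on fewer libraries than the means of other groups. For controls 1 and 3 the own-group mean also includes control 2, which can lower their values. Swimming 2 was low for muscle (-2.476), T cells (-1.763), natural killer cells (-1.614) and B cells (-1.547). Adipocyte markers were highest in the combination libraries (1.05, 1.062 and 1.061), which also had the lowest neutrophil levels (-0.939, -0.874 and -1.086). The labels do not state whether the pieces were trimmed of muscle, fat or skin, so the muscle and adipocyte values cannot be separated from dissection. Mitochondrial transcripts made up 3.683 ± 0.68% of counts in control, 3.759 ± 0.373% in curcumin, 4.604 ± 0.256% in swimming and 5.331 ± 0.672% in combination (n = 3 each). The mitochondrially encoded and ribosomal protein lists were fixed as indicators of RNA quality. Whether their shifts reflect treatment or sample quality was not tested. The biological coefficient of variation was 23.5% in control, 12% in curcumin, 15.4% in swimming and 6.43% in combination.

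**Figure D1:**
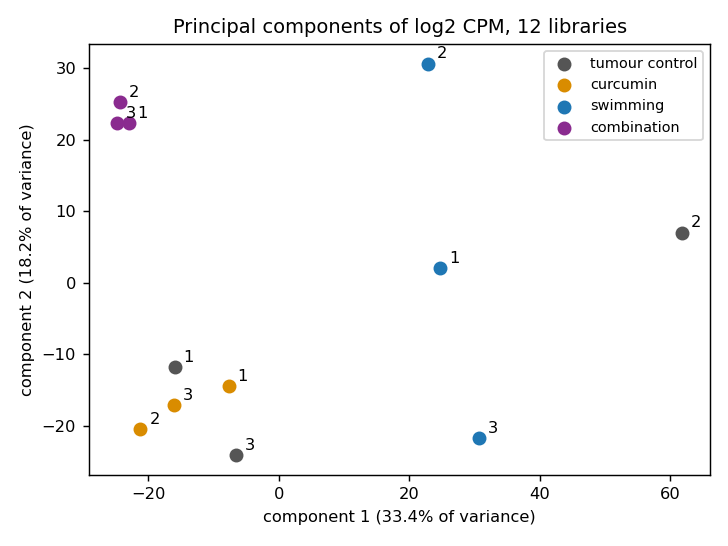
Each point is a library, coloured by group, on the first principal component (33.4% of variance) against the second component (18.2%). The combination libraries lay close together (-23.04, -24.37 and -24.82 on the horizontal axis), and control 2 lay furthest from the rest at 61.81.

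Curcumin alone was set against tumour control to ask what the polyphenol did without exercise. All 21 measured genes of the type I interferon list had positive changes (median 0.48), as did all 20 of the interferon-gamma list (median 0.46). Oas2 (ENSMUSG00000032690), a sensor of double-stranded RNA, stood at 0.78 ± 0.17 (adjusted p = 0.24). Cxcl10, a chemokine for T cells, measured 63.3 ± 2.75 CPM against 34.5 ± 5.64 (0.88 ± 0.17, adjusted p = 0.18). Adjusted over the list alone, 14 members of each interferon list passed, while 0 passed over all genes. The 2 lists passed camera at adjusted p = 1.04e-13 and 8.34e-12. Here and for the lists that follow, adjusted p = 0.77 with an estimated correlation, and fry called 0. Ribosomal protein genes had 0 of 28 positive changes (median -0.23, camera adjusted p = 1.23e-07), with Rps6 at -0.33 (adjusted p = 0.36). Cell cycle genes had 27 of 28 positive (median 0.46, camera adjusted p = 1.23e-07), with Cdk1 at 0.47 ± 0.22 (adjusted p = 0.46). Collagens and matrix genes (median 0.51, adjusted p = 0.00022) and skeletal muscle genes (0.55, adjusted p = 0.00103) also passed camera. In each of these 4 lists 0 genes were called over all genes and 0 adjusted over the list alone.

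The genes with the smallest p after curcumin did not pass. Lamc3 (ENSMUSG00000026840, chromosome 2, 31777303 to 31836551), a laminin chain of basement membranes, measured 9.55 ± 0.709 CPM against 1.25 ± 0.614 (2.93 ± 0.40, adjusted p = 0.068). Slc15a3, a peptide and histidine transporter of lysosomes, measured 125.0 ± 4.18 against 79.2 ± 11.2 (0.66 ± 0.09, adjusted p = 0.068). Grem1 (ENSMUSG00000074934), a secreted antagonist of bone morphogenetic proteins, measured 107 ± 14.9 against 36.1 ± 6.85 (1.57 ± 0.23, adjusted p = 0.1). Epcam, the epithelial adhesion molecule, measured 261 ± 8.65 against 339 ± 26.6 (-0.37 ± 0.08, adjusted p = 0.19). Smaller list shifts past camera were NF-kB targets (median 0.19, adjusted p = 0.0105), cholesterol synthesis (0.21, 0.0107), macrophages (0.26, 0.0107) and MHC class I (0.16, 0.0194). Nrf2 targets followed (0.07, 0.0363), with Me1 at 0.61 and adjusted p = 0.1. Lower medians belonged to tumour epithelial markers (-0.17, 0.0186), heat shock (-0.21, 0.0186) and immediate early genes (-0.27, 0.0399). Adjusted p was 0.77 with an estimated correlation for each of the 14 lists past camera.

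For curcumin versus tumour control, edgeR called 0 genes, with 1490 at unadjusted p under 0.05. DESeq2 called 76 genes, and limma voom called 3 with a common spread and 0 with a weight per group. The count was 5, 8 and 1 without control 1, control 2 and control 3, and 6 and 2 without swimming 2 and swimming 3. Without control 2 the type I interferon list (median 0.5), cell cycle (0.14), ribosomal proteins (-0.08) and NF-kB targets (0.54) still passed camera. Lists no longer past it were collagens (0.2, adjusted p = 0.12), muscle (0.01, 0.96), cholesterol synthesis (-0.05, 0.5), macrophages (0.1, 0.24), MHC class I (0.06, 0.24), heat shock (-0.08, 0.28), immediate early genes (-0.12, 0.75) and tumour epithelial markers (-0.01, 0.27). Part of the interferon-gamma shift also rests on control 2. That level was -0.55 in control 2, 0.099 and -0.092 in controls 1 and 3, and 0.093 to 0.567 under curcumin.

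**Figure D2:**
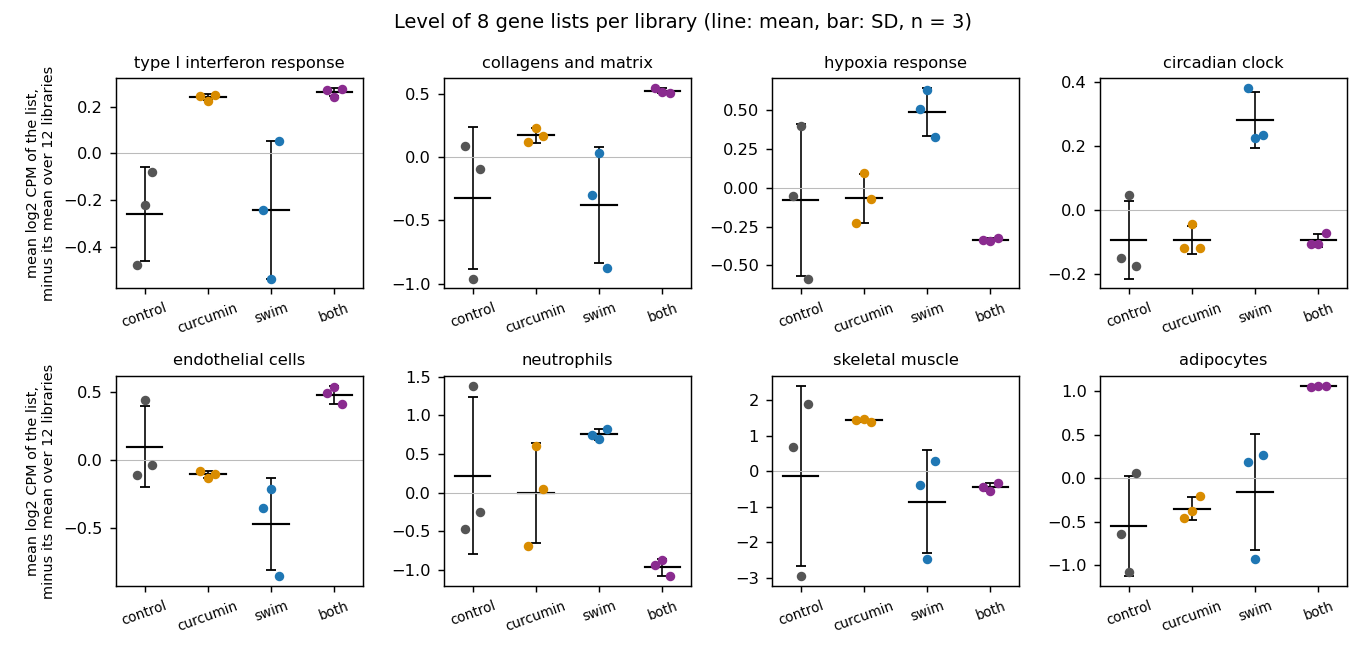
Points are libraries, with group mean and SD as bars, for the mean level of 8 gene lists (type I interferon, collagens, hypoxia, clock, endothelial, neutrophil, muscle and adipocyte) on the vertical axis. Endothelial level ran from -0.852 to -0.212 in swimming and from 0.407 to 0.538 in combination.

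Swimming alone raised the clock genes Per1 and Bhlhe41 and lowered Ptprb, S1pr2 and Slc6a2 relative to tumour control. Per1 (ENSMUSG00000020893, chromosome 11, 68986043 to 69000786), a negative arm of the circadian clock, rose by 1.75 ± 0.30 (adjusted p = 0.044), reaching 212 ± 52.3 CPM. Bhlhe41, a clock repressor, rose from 26 ± 2.49 to 49.8 ± 4.4 CPM (0.94 ± 0.14, adjusted p = 0.022). Ptprb (ENSMUSG00000020154, chromosome 10, 116111428 to 116225440), the endothelial tyrosine phosphatase that acts on Tie2, fell from 28.6 ± 1.95 to 12.7 ± 0.893 CPM (-1.18 ± 0.13, adjusted p = 0.0051). S1pr2, a sphingosine 1-phosphate receptor, fell with it (-0.81 ± 0.09, adjusted p = 0.0051), as did the water channel Aqp1 (-1.18 ± 0.15, adjusted p = 0.0098), the junction molecule Jam2 (-1.66) and the vascular homeobox gene Meox2 (-1.3). Slc6a2 (ENSMUSG00000055368), the noradrenaline transporter, fell by 3.67 ± 0.52 (adjusted p = 0.022), and the IL-33 receptor Il1rl1 fell by 1.3. Other called increases were D7Ertd443e (3.09), the sodium-proton exchanger Slc9a4 (2.08), the costimulatory ligand Cd80 (1.42), Cytip (1.3), Trem1 (1.07) and the engulfment receptor Mertk (0.86).

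Hypoxia genes had 17 of 17 positive changes after swimming (median 0.5, camera adjusted p = 1.13e-08), with 0 called over all genes and 7 adjusted over the list alone. Vegfa, the main vascular growth factor, stood at 0.79 (adjusted p = 0.13) and the oxygen sensor Egln1 at 0.43 (adjusted p = 0.072). Glycolysis genes had 15 of 17 positive (median 0.38, camera adjusted p = 6.21e-08), with 0 called and 10 adjusted over the list alone. Pgk1, which makes ATP in that pathway, stood at 0.61 (adjusted p = 0.084). NF-kB targets (median 0.49, camera adjusted p = 3.93e-06) had 0 called and 3 adjusted over the list alone, with Il1a at 1.17 and adjusted p = 0.064. Endothelial genes had 1 of 17 positive (median -0.69, camera adjusted p = 4.63e-07), with 0 called and 9 lower adjusted over the list alone. Its members Pecam1 (-0.75, adjusted p = 0.053), Tek (-1.51, 0.059) and Plvap (-0.76, 0.064) lay just outside the threshold. The clock list (median 0.33, camera adjusted p = 0.00011) held 2 called genes, 5 adjusted over the list alone. Further lists past camera were cholesterol synthesis (0.26), mitochondrially encoded genes (0.28), immediate early genes (0.29), macrophages (-0.45) and MHC class II (-0.38). Adjusted p ran from 0.062 (clock) to 0.65 with an estimated correlation, and fry called only the clock (adjusted p = 0.0036). No Gene Ontology term passed among the genes called higher (smallest adjusted p = 0.95) or lower (1).

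In swimming versus tumour control, edgeR called 42 genes (21 higher, 21 lower, 1770 at unadjusted p under 0.05) and DESeq2 called 310, whereas a fit of the 2 groups alone and limma voom with a weight per group each called 0, a replicate block left 4 and summing the combination libraries left 3. The count became 9, 603 and 8 without control 1, control 2 and control 3, 18, 26 and 8 without curcumin 1, curcumin 2 and curcumin 3, 0 and 24 without swimming 1 and swimming 3, and 5, 16 and 5 without combination 1, combination 2 and combination 3. Every gene named as called here lost its call without swimming 1, while hypoxia (median 0.85), clock (0.35) and endothelial lists (-0.5) kept theirs without control 2. Cholesterol synthesis level was -1.039 in control 2, 0.18 and -0.037 in controls 1 and 3, and 0.059, 0.155 and -0.022 in swimming. Its shift therefore rests mainly on control 2. Mitochondrially encoded genes were also lowest in control 2 (-0.585, against -0.216 and -0.019 in controls 1 and 3).

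With curcumin and swimming together, 12 of 21 type I interferon genes and 4 of 20 matrix genes were called higher than in tumour control, and 3 of 12 neutrophil genes lower. The interferon list did not pass camera between combination and curcumin alone (median 0.04, 13 of 21 positive, 0 called, adjusted p = 0.66). The larger number of calls is therefore no evidence of a stronger interferon shift than under curcumin. Against control, Lamc3 rose to 10.4 ± 1.79 CPM (3.05 ± 0.40, adjusted p = 0.0058). Oas2 (chromosome 5, 120868398 to 120887918) rose from 58.6 ± 16.4 to 112 ± 1.88 CPM (0.93 ± 0.17, adjusted p = 0.019). The related Oas3 (0.78 ± 0.13, adjusted p = 0.015), the interferon-induced Ifi44 (0.82, 0.023) and the RNA sensor Ddx58 (0.55, 0.031) rose with it. Loxl2, which crosslinks collagen, rose from 46.5 ± 8.06 to 109 ± 2.49 CPM (1.23 ± 0.22, adjusted p = 0.019), beside tenascin Tnc (1.32 ± 0.26, 0.026), Sparc (0.76, 0.034) and biglycan Bgn (1.05, 0.044). Tgfb2, an inducer of mesenchymal change, rose from 9.42 ± 1.29 to 28.8 ± 3.92 CPM (1.61 ± 0.24, adjusted p = 0.0095), and the transcription factor Zeb1 rose by 0.69 (0.034). S100a8, a neutrophil alarmin, fell from 9.62 ± 9.83 to 1.37 ± 0.0342 CPM (-2.8 ± 0.70, adjusted p = 0.048), and Retnlg fell by 3.12 ± 0.58 (0.019).

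Type I interferon genes had 20 of 21 positive in the combination (median 0.55, camera adjusted p = 2.98e-08), with 12 called, 14 adjusted over the list alone. Collagens and matrix genes were positive for 20 of 20 (median 0.77, adjusted p = 4.01e-07), with 4 called, 9 adjusted over the list alone. Cell cycle genes were positive for 28 of 28 (median 0.57, adjusted p = 6.68e-07) with 0 called and 0 adjusted over the list alone. Ribosomal protein genes had a median of -0.38 (adjusted p = 2.56e-06), with Rplp1 (-0.75) and Rps14 (-0.7) called, 17 adjusted over the list alone. Mitochondrially encoded genes were positive for 10 of 10 (median 0.53, adjusted p = 1.8e-05), with mt-Nd5 (1.01 ± 0.21), mt-Nd6 (1.96), mt-Nd2 (0.7) and mt-Co1 (0.55) called, 9 adjusted over the list alone. Neutrophil genes had a median of -1.63 (adjusted p = 0.00135) with 3 called, 8 lower adjusted over the list alone, among them the histone citrullinating enzyme Padi4 (-0.55). Adipocyte genes had a median of 0.78 (adjusted p = 0.00795) with 2 called, 4 adjusted over the list alone. Cfd, adipsin, had 155 counts against 2 in control (ratio 80.2, interval 21.8 to 668), Cidec 86 against 1 (ratio 89, 15.6 to 3560), and Pck1 64 against 0 (at least 22.1-fold). Adjusted p ran from 0.73 to 0.84 with an estimated correlation over the 15 lists past camera, and fry called only adipocytes (0.037).

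Smaller shifts past camera in the combination were mesenchymal transition (median 0.24), Wnt targets (0.48), endothelial cells (0.42, with Emcn called at 1.0), fibroblasts (0.31), cholesterol synthesis (0.37), dendritic cells (-0.43) and macrophages (-0.43). The interferon-gamma list passed upward (median 0.31, adjusted p = 0.0352), although Irf1 within it fell (-0.37 ± 0.09, adjusted p = 0.041). Slc6a2 had 2 counts against 214 in control, 103-fold lower (28.3 to 859). Other large called changes were Avpr1a (2.85), Osbp2 (2.86), Gucy2f (3.44), Atf7ip2 (3.73), Zfp804a (3.14), Scara5 (-2.97), Lilra6 (-3.35), Fcna (-2.66), Igfbp2 (-2.65), Smoc1 (-2.43) and Cilp2 (-2.27). Among called higher genes, negative regulation of viral genome replication held 8 of 35 tested (adjusted p = 0.0036) and defense response to virus held 14 of 141 (adjusted p = 0.011).

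In combination versus tumour control, edgeR called 663 genes (332 higher, 331 lower), DESeq2 1628 and a fit of the 2 groups alone 132, but summing the 3 combination libraries into 1 left 0 of the 663, with 1 sample in that group. The count was 2182, 316 and 324 without control 1, control 2 and control 3, 392 and 179 without curcumin 1 and curcumin 3, 273 without swimming 1, and 20, 10 and 4 without combination 1, combination 2 and combination 3. Without control 2, cell cycle (median 0.25), neutrophils (-0.72) and cholesterol synthesis (0.1) were smaller but past camera (adjusted p = 0.00072, 0.026 and 0.038), and interferon-gamma (adjusted p = 0.46) and fibroblasts (adjusted p = 0.41) no longer passed. Of the named genes, Lamc3 and Slc6a2 kept their calls without each library in turn.

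**Figure D3:**
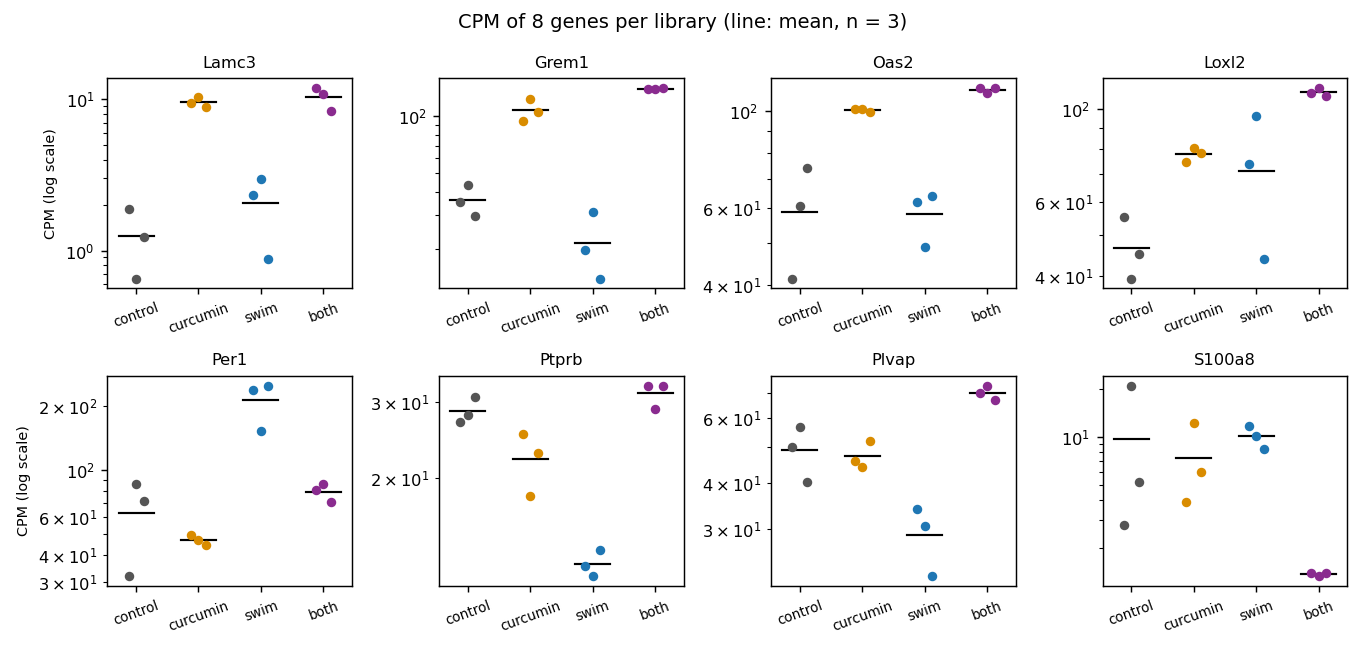
Points are single libraries and lines are group means, on a log axis of CPM, for Lamc3, Grem1, Oas2, Loxl2, Per1, Ptprb, Plvap and S100a8. Lamc3 measured 1.25 ± 0.614 in control, 9.55 ± 0.709 in curcumin, 2.07 ± 1.08 in swimming and 10.4 ± 1.79 in combination.

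Adding swimming to curcumin was examined by setting the combination against curcumin alone. Fmod (ENSMUSG00000041559, chromosome 1, 133964992 to 133976015), a proteoglycan that organises collagen fibrils, rose from 6.39 ± 1.61 to 27.1 ± 2.41 CPM (2.09 ± 0.22, adjusted p = 0.003). Nr4a1 (ENSMUSG00000023034, chromosome 15, 101152150 to 101172676), an immediate early nuclear receptor, rose from 23.2 ± 3.24 to 56.9 ± 4.86 CPM (1.29 ± 0.15, adjusted p = 0.0039). The AP-1 gene Fosb (1.89 ± 0.31, adjusted p = 0.027), the fibrillar collagen Col11a1 (2.14 ± 0.36, 0.026) and the epithelial splicing regulator Esrp2 (0.89, 0.03) also rose. Scavenger and lipid receptors of macrophages fell: Msr1 from 203 ± 29.8 to 111 ± 6.94 CPM (-0.86 ± 0.13, adjusted p = 0.015) and Trem2 by 1.06 ± 0.21 (0.038). Irf1, a mediator of interferon-gamma signals, fell from 214 ± 23.3 to 131 ± 4.51 CPM (-0.71 ± 0.09, adjusted p = 0.011). The adhesion molecule Selp fell by 2.12 (0.028), the myeloid hexokinase Hk3 by 1.41 (0.048) and Cwc22 by 2.29 ± 0.30 (0.015). Slc6a2 had 2 counts against 49 under curcumin, 25.2-fold lower (6.62 to 214).

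Macrophage genes had a median of -0.69 in this comparison (camera adjusted p = 8.29e-06) with 2 called, 6 adjusted over the list alone. Mitochondrially encoded genes had 0.57 (5.12e-06) with 0 called and 9 adjusted over the list alone. Endothelial genes were positive for 15 of 17 (0.57, 1.96e-05) with 0 called and 7 adjusted over the list alone. Muscle genes had -1.82 (0.000372) with 0 called and 1 adjusted over the list alone, and adipocyte genes 0.84 (0.000405) with 1 called, 4 adjusted over the list alone. Cidec had 86 counts against 0 under curcumin (at least 27.8-fold). Neutrophils (-1.38), NF-kB targets (-0.57), dendritic cells (-0.53), MHC class II (-0.42), Nrf2 targets (-0.27), glycolysis (-0.26), hypoxia (-0.26), interferon-gamma (-0.25), MHC class I (-0.21), oxidative phosphorylation (-0.13) and mast cells (-2.61) passed camera downward. Collagens (0.33), immediate early genes (0.31), mesenchymal transition (0.21) and tumour epithelial markers (0.17) passed upward. With an estimated correlation, adjusted p ran from 0.4 to 0.66 over the 20 lists, and fry called only adipocytes (0.03). Phagocytosis and engulfment was over-represented among called lower genes (4 of 20, adjusted p = 0.0027).

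In combination versus curcumin alone, edgeR called 116 genes (49 higher, 67 lower) and DESeq2 686, against 28 with a replicate block and 0 with the combination libraries summed. The count was 225 and 715 without control 1 and control 2, 3 and 8 without curcumin 2 and curcumin 3, 77, 210 and 205 without swimming 1, swimming 2 and swimming 3, and 5, 3 and 3 without combination 1, combination 2 and combination 3. A fit of only the groups compared and limma voom with a weight per group each called more than the 116, as given below. Fmod and Nr4a1 kept their calls without each library in turn.

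Against swimming alone, 9 of 17 endothelial genes were called higher in the combination and 9 of 17 hypoxia genes lower. Aplnr (ENSMUSG00000044338, chromosome 2, 84966569 to 84970267), the apelin receptor of growing vessels, rose from 3.22 ± 1.93 to 29.3 ± 2.5 CPM (3.19 ± 0.33, adjusted p = 0.0012). Plvap (ENSMUSG00000034845, chromosome 8, 71950409 to 71964396), the diaphragm protein of fenestrated endothelium, rose to 70.2 ± 3.04 CPM (1.27 ± 0.15, adjusted p = 0.0033). Emcn (1.62 ± 0.22), Pecam1 (1.03, adjusted p = 0.006), the angiopoietin receptor Tek (1.97, 0.0081), the pericyte gene Rgs5 (1.63) and Cd34 (1.41) rose as well. Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell from 102.0 ± 5.89 to 51.1 ± 4.25 CPM (-1.0 ± 0.14, adjusted p = 0.006). Hexokinase Hk2 fell from 208 ± 3.76 to 116 ± 6.62 CPM (-0.85 ± 0.13, adjusted p = 0.008), with Ddit4 (-1.28), Ero1a (-1.03), Kdm3a (-0.6), Aldoc (-0.69), Pfkl (-0.82) and Pgk1 (-0.64). Csf3, the neutrophil growth factor, fell by 1.14 ± 0.20 (adjusted p = 0.012) and the NF-kB inhibitor Nfkbia fell by 1.13. The stress regulators Trib3 (-1.71) and Atf4 (-0.69) and the clock genes Per1 (-1.43), Cry2 (-0.96), Nr1d2 (-0.51) and Tef (-0.42) fell too.

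Hypoxia genes had 0 of 17 positive against swimming (median -0.81, camera adjusted p = 7.85e-09) with 9 called, 16 adjusted over the list alone. Glycolysis genes had a median of -0.52 (6.44e-08) with 7 called, 13 adjusted over the list alone. Endothelial genes were positive for 16 of 17 (0.91, 6.44e-08) with 9 called, 11 adjusted over the list alone, and fry gave adjusted p = 0.011. Type I interferon genes were positive for 21 of 21 (0.5, 8.03e-08) with 8 called, 15 adjusted over the list alone, including Oas2 (0.94), Cmpk2 (0.97), Ifit2 (0.79) and Rsad2 (0.96). Collagens (0.9, 8.03e-08) held 2 called genes, 13 adjusted over the list alone, with Sparc at 0.91 and Tnc at 1.18. Neutrophils (-1.91, 1.55e-06) held 5 called, 10 adjusted over the list alone, with S100a8 at -2.87 and S100a9 at -2.88. The clock (-0.54, 0.000993) held 7 called, 12 lower adjusted over the list alone, with fry adjusted p = 0.0013. Adjusted p ran from 0.18 (clock) to 0.77 with an estimated correlation over the 19 lists past camera, of which fry called 12.

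Other lists past camera against swimming were fibroblasts (0.84), cell cycle (0.45), mesenchymal transition (0.3), Wnt targets (0.28), interferon-gamma (0.27), mitochondrially encoded genes (0.23) and adipocytes (0.91). Downward lists were ribosomal proteins (-0.3), NF-kB targets (-0.42), Nrf2 targets (-0.31), the unfolded protein response (-0.19) and fatty acid synthesis (-0.15), whose called members were led by Srebf1 (-0.44) and Acss2 (-0.7). Fabp4 (1.21), Plin4 (2.84), Epha3 (3.05), Rflna (3.11) and the Wnt feedback genes Nkd2 (1.51) and Rnf43 (1.29) rose, and the B cell gene Bank1 fell by 3.59. Col9a1 had 93 counts against 2 (ratio 43.8, 11.8 to 367). Angiogenesis held 30 of 225 tested genes among those called higher (adjusted p = 7.4e-07), extracellular matrix organization 15 of 129 (0.018), and glycolytic process 7 of 25 among those called lower (0.02).

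In combination versus swimming alone, edgeR called 908 genes (478 higher, 430 lower) and DESeq2 1842, and 0 remained with the combination libraries summed. The count was 1639 and 2697 without control 1 and control 2, 467 without curcumin 3, 109 and 161 without swimming 1 and swimming 3, and 89, 31 and 81 without combination 1, combination 2 and combination 3. More than the 908 were called by a fit of only the groups compared and by limma voom with a weight per group, as given below. Aplnr, Plvap, Emcn, Pecam1, Tek and Pdk1 kept their calls without each library in turn.

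The interaction asked whether the combination departed from the sum of the separate effects on the log scale. Plvap measured 70.2 ± 3.04 CPM in combination and had an interaction of 1.32 ± 0.22 (adjusted p = 0.034), beside Aplnr (2.64 ± 0.44, 0.043), Pecam1 (1.14, 0.047), Ptprb (1.69) and Meox2 (2.03). Fmod had 2.16 ± 0.31 (adjusted p = 0.022) and Aspa, which splits N-acetylaspartate, had 3.04 ± 0.43 (0.022), at 7.46 ± 0.532 CPM against 0.937 ± 0.121 to 1.88 ± 0.562 in the other groups. Slpi, an inhibitor of neutrophil proteases, had -1.63 ± 0.23 (adjusted p = 0.022), at 6.42 ± 0.475 CPM in combination against 20.9 ± 1.97 in swimming. Alox5, the leukotriene enzyme (-3.0 ± 0.55, 0.048), the leukocyte integrin Itgb2 (-1.28, 0.026), Dok2 (-1.3, 0.038), Irf1 (-0.72, 0.048) and Cwc22 (-2.94, 0.026) were also below the sum. Tek (2.14), Pdk1 (-1.04) and Pgk1 (-0.99) each had adjusted p = 0.056.

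Endothelial genes were above the sum for 17 of 17 (median 1.14, camera adjusted p = 1.11e-12) with 2 called, 11 adjusted over the list alone. Hypoxia (-0.76, 1.1e-09), glycolysis (-0.58, 1.37e-09) and NF-kB targets (-1.0, 7.65e-09) were below it with 0 called in each, and 6, 9 and 5 adjusted over the list alone. Neutrophils (-1.66), Nrf2 targets (-0.4), the clock (-0.45), MHC class I (-0.25), interferon-gamma (-0.25), the unfolded protein response (-0.19), fatty acid synthesis (-0.19) and oxidative phosphorylation (-0.11) also passed camera downward. Interferon-gamma level was -0.55 in control 2 against 0.099 and -0.092 in controls 1 and 3, so this departure rests mainly on control 2. Collagens (0.49), adipocytes (0.48), fibroblasts (0.47) and tumour epithelial markers (0.05) passed upward. Over the 16 lists, adjusted p was 0.15 to 0.6 with an estimated correlation, and fry called the clock (0.02) and endothelial cells (0.033). Angiogenesis held 6 of 225 tested genes among those above the sum (adjusted p = 0.0024), and no term passed among those below it (smallest adjusted p = 0.08).

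For the interaction of curcumin and swimming, edgeR called 34 genes (22 above, 12 below) and DESeq2 210, against 11 with a replicate block and 0 with the combination libraries summed. The count was 455 and 22 without control 2 and control 3, 16, 6 and 1 without curcumin 1, curcumin 2 and curcumin 3, 0, 97 and 17 without swimming 1, swimming 2 and swimming 3, and 1 without each of combination 1, combination 2 and combination 3. None of the named genes kept its call without each library in turn.

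Averaged over both exercise states, curcumin raised Grem1 and Lamc3. Grem1 (chromosome 2, 113576509 to 113588991) rose by 2.13 ± 0.17 (adjusted p = 0.00072) and Lamc3 by 2.63 ± 0.28 (0.0024). Oas2 rose by 0.86 ± 0.12 (adjusted p = 0.0082), with the antiviral kinase Cmpk2 (0.86, 0.0097), Ifit2 (0.72), Oas3 (0.55), Cxcl10 (0.68 ± 0.12, 0.018), Irgm2 (0.48) and Gbp5 (0.54). Matrix genes Sparc (0.61), Tnc (0.89), Loxl2 (0.68) and Col12a1 (0.91) rose, as did the endothelial genes Plvap (0.61), Emcn (0.81) and Kdr (0.8) and the Wnt feedback gene Axin2 (1.09). The vasopressin receptor Avpr1a (1.99, adjusted p = 0.0082), the retinoid binding protein Crabp1 (1.92) and Adamtsl2 (2.12) rose further. The death mediator Bcl2l11 fell by 0.62 (adjusted p = 0.014), and Pdk1 (-0.48), Hk2 (-0.44), Ddit4 (-0.77), Per1 (-0.92), Fn1 (-0.53), Spp1 (-0.42), Rps9 (-0.4) and Retnlg (-2.21) fell. Larger called decreases were A3galt2 (-1.61), Mef2b (-1.57), Col11a2 (-1.03), the granzyme Gzmc (-0.97) and Plekhg6 (-0.89). Without swimming, curcumin against control left the endothelial list at a median of -0.17 (2 of 17 positive). The hypoxia list stood at -0.1 (5 of 17 positive), and neither list passed camera (adjusted p = 0.0665 and 0.96). The averaged endothelial and hypoxia shifts therefore rest mainly on the swimming state. The clock (median 0.02), glycolysis (-0.01) and neutrophils (-0.23) did not pass camera without swimming either (adjusted p = 0.926, 0.65 and 0.228). In combination against swimming alone their medians were -0.54, -0.52 and -1.91, so their averaged shifts rest mainly on that state too.

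Type I interferon genes were positive for 21 of 21 over the averaged curcumin effect (median 0.5, camera adjusted p = 7.92e-12) with 13 called, 19 adjusted over the list alone, and fry gave adjusted p = 0.023. Interferon-gamma genes (0.39, 9.61e-07) held 5 called, 12 adjusted over the list alone. Collagens (0.69, 1.08e-07) held 8 called, 16 adjusted over the list alone. Ribosomal proteins (-0.27, 1.08e-07) held 5 called lower, 20 adjusted over the list alone, and cell cycle genes (0.47, 7.35e-07) held 0 called and 0 adjusted over the list alone. Hypoxia (-0.43, 1.23e-05) held 3 called lower, 12 adjusted over the list alone, and the clock (-0.23, 0.0136) held 4, 7 adjusted over the list alone, with fry adjusted p = 0.015. Neutrophils (-0.97), glycolysis (-0.23), fibroblasts (0.58), endothelial cells (0.35), Wnt targets (0.29), mesenchymal transition (0.14) and muscle (0.12) passed camera as well. The muscle and cell cycle averages lean on control 2. Its muscle level was -2.958 (0.688 and 1.898 in controls 1 and 3) and its cell cycle level -1.1 (0.116 and -0.013). Adjusted p ran from 0.56 to 0.77 with an estimated correlation over the 14 lists. Defense response to virus held 20 of 141 tested genes among those called higher (adjusted p = 4.5e-05), and extracellular matrix organization 17 of 129 (0.00052).

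For curcumin averaged over swimming, edgeR called 885 genes (430 higher, 455 lower) and DESeq2 1971, and 1 with the combination libraries summed. The count was 2595 without control 1, 410, 221 and 17 without curcumin 1, curcumin 2 and curcumin 3, 84 and 366 without swimming 1 and swimming 3, and 63, 49 and 17 without combination 1, combination 2 and combination 3. Grem1, Lamc3, Avpr1a, Oas2 and Cmpk2 kept their calls without each library in turn.

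Averaged over both curcumin states, swimming lowered Slc6a2 and raised the immediate early genes Nr4a1 and Fosb. Slc6a2 (chromosome 8, 93686707 to 93728295) measured 4.24 ± 0.807, 1.03 ± 0.289, 0.324 ± 0.167 and 0.0404 ± 0.0699 CPM in control, curcumin, swimming and combination, and fell by 4.05 ± 0.45 (adjusted p = 0.0031). Nr4a1 rose by 0.79 ± 0.10 (adjusted p = 0.0085) and Fosb by 1.38 ± 0.22 (0.022). The clock genes Bhlhe41 (0.72, adjusted p = 0.011) and Per1 (1.25, 0.022) rose and Tef fell (-0.33). Macrophage genes Trem2 (-0.88 ± 0.15, 0.022), the complement receptor C3ar1 (-0.89), Fcgr1 (-0.67) and Msr1 (-0.42) fell, beside the cytokine signal inhibitor Socs1 (-0.88), Irf1 (-0.35), Fam20c (-1.03) and Tcte2 (-1.08). Muscle genes Pvalb (-4.13) and Myh4 (-5.03) fell, in a setting where muscle level ran from -2.958 to 1.898 within control alone and trimming of the pieces is not stated. The decoy receptor Il1r2 (1.47), Gucy2f (2.76), Tent5b (1.0), mt-Co1 (0.48) and mt-Nd2 (0.6) rose.

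Macrophage genes had a median of -0.66 over the averaged swimming effect (camera adjusted p = 8.45e-07) with 3 called, 13 adjusted over the list alone. Mitochondrially encoded genes had 0.43 (8.45e-07) with 2 called, 9 adjusted over the list alone. Muscle genes had 0 of 19 positive (-1.41, 0.000751) with 2 called, 5 adjusted over the list alone. Immediate early genes (0.27, 0.00289) held 2 called, 3 adjusted over the list alone, and adipocytes (0.27, 0.00407) held 2, 2 adjusted over the list alone, with fry adjusted p = 0.048. Cholesterol synthesis (0.19), hypoxia (0.12), MHC class II (-0.38), interferon-gamma (-0.18) and dendritic cells (-0.35) passed camera too. The hypoxia average joins opposite shifts, with a median of 0.5 in swimming versus control and -0.26 in combination versus curcumin. The clock (median 0.17) did not pass camera (adjusted p = 0.0593) but passed fry (0.048). The 10 lists past camera had adjusted p from 0.59 to 0.81 with an estimated correlation. Phagocytosis and engulfment held 5 of 20 tested genes among those called lower (adjusted p = 0.0042), and peptidyl-threonine dephosphorylation 4 of 20 among those called higher (0.039).

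For swimming averaged over curcumin, edgeR called 277 genes (129 higher, 148 lower) and DESeq2 929, and 0 with the combination libraries summed. The count was 571, 976 and 129 without control 1, control 2 and control 3, 49 and 18 without curcumin 2 and curcumin 3, 7 without swimming 1, and 30, 6 and 11 without combination 1, combination 2 and combination 3. Slc6a2 and Nr4a1 kept their calls without each library in turn.

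Swimming and curcumin taken singly were then set against each other, in a comparison free of the control libraries except through the shared spread. Per1 was higher under swimming by 2.18 ± 0.31 (adjusted p = 0.014), as were Bhlhe41 (0.94, 0.014), the clock receptor Nr1d1 (0.89, 0.045) and Slc9a4 (2.19). Interferon targets were lower, among them Cxcl10 (-1.04 ± 0.17, adjusted p = 0.018), Cmpk2 (-0.98, 0.023), Ifit2 (-0.81), Oas2 (-0.79), Irgm2 (-0.67), Gbp5 (-0.76) and Socs1 (-1.4 ± 0.22, 0.016). Igf1 measured 1.28 ± 0.199 CPM under swimming and 9.7 ± 1.85 under curcumin (-2.91 ± 0.53, adjusted p = 0.027). The incretin receptor Glp1r (-2.82, 0.014), Wnt4 (-3.35), Trem2 (-1.12), Fcgr1 (-0.92) and the monocyte receptor Ccr2 (-1.47) were lower too, with the vascular genes Plvap (-0.71), Tek (-1.34), Pecam1 (-0.63) and Rgs5 (-1.29). Il1r2 (2.03), Dlx3 (2.29), Ky (2.03), Kdm3a (0.6) and Rps18 (0.71) were higher. Pvalb had 1 count under swimming against 87 under curcumin (84.4-fold, 14.7 to 3370) and Myod1 2 against 61 (29.6-fold, 7.84 to 250). Muscle level ran from -2.476 to 0.289 in swimming and from 1.384 to 1.457 in curcumin, and trimming of the pieces is not stated. These muscle differences therefore cannot be separated from dissection.

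All 21 type I interferon genes lay lower under swimming than curcumin (median -0.45, camera adjusted p = 1.26e-07) with 3 called, 15 adjusted over the list alone, as did all 20 interferon-gamma genes (-0.52, 2.27e-07) with 4 called, 12 adjusted over the list alone. Hypoxia genes (0.59, 1.08e-06) held 1 called, 9 adjusted over the list alone, and glycolysis (0.33, 3.17e-05) held 0, 7 adjusted over the list alone. Macrophages (-0.71, 4.61e-06) held 3 called, 10 adjusted over the list alone, and muscle (-1.42, 6.66e-05) held 1, 4 adjusted over the list alone. The clock (0.34, 0.00117) held 3 called, 7 adjusted over the list alone, with fry adjusted p = 0.0031. Immediate early genes (0.47), neutrophils (0.5), mitochondrially encoded genes (0.27) and ribosomal proteins (0.16) passed upward. MHC class II (-0.64), collagens (-0.48), fibroblasts (-0.57), endothelial cells (-0.29), natural killer cells (-0.84) and cell cycle (-0.33) passed downward. Natural killer level was -1.614 in swimming 2, against -0.309 and 0.388 in swimming 1 and 3. Cell cycle level was -0.553 in swimming 3, against -0.125 and 0.169 in swimming 1 and 2. The natural killer and cell cycle shifts therefore lean partly on single libraries. Adjusted p ran from 0.17 to 0.74 with an estimated correlation over the 17 lists. Angiogenesis held 10 of 225 tested genes among those called lower (adjusted p = 0.04), and inflammatory response 10 of 261 (0.04).

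For the difference of response between curcumin and swimming, edgeR called 243 genes (120 higher under swimming, 123 lower) and DESeq2 1016, against 57 with a replicate block and 10 with the combination libraries summed. The count was 535 and 1537 without control 1 and control 2, 142, 14 and 11 without curcumin 1, curcumin 2 and curcumin 3, 9 and 102 without swimming 1 and swimming 3, and 67, 67 and 65 without combination 1, combination 2 and combination 3. More than the 243 were called by a fit of only the groups compared and by limma voom with a weight per group, as given below. None of the named genes kept its call without swimming 1.

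Of 10 genes often read in breast tumours (Mki67, Epcam, Vegfa, Il6, Tnf, Hmox1, Ptgs2, Cd8a, Gzmb and S100a8), only S100a8 was called, lower in the combination against control (-2.8) and against swimming (-2.87). In control the SD of S100a8 was above its mean. Neutrophil level was 1.386 in control 2, against -0.469 and -0.257 in controls 1 and 3. The fall against control may therefore lean on control 2. Against control, the 10 ran from -0.39 (S100a8) to 1.05 (Il6) under curcumin and from -0.4 (Cd8a) to 1.24 (Il6) under swimming. In the combination the highest was again Il6 (1.28).

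**Figure D4:**
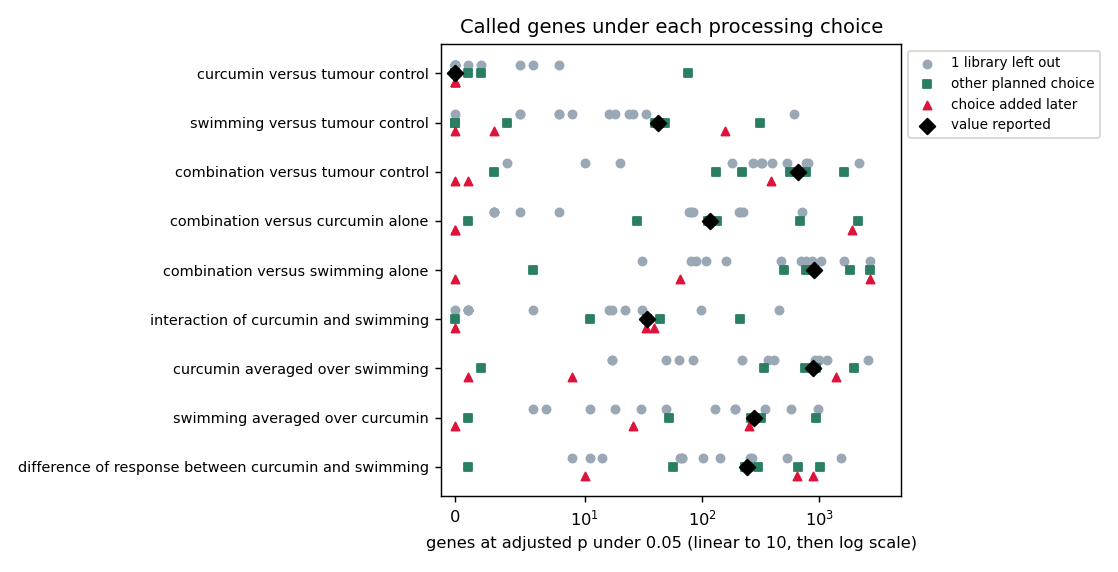
The number of called genes under each processing choice is shown per comparison on a symmetric log axis, with the reported fit among the choices. For combination versus tumour control the number was 663 in the reported fit, 1628 with DESeq2 and 0 with the combination libraries summed.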

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

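The departures from additivity were found by a rule fixed beforehand, while the order in which they are told was chosen after the result was seen. Curcumin and swimming together departed from the sum of their separate effects at 34 genes. Named genes above the sum were Aspa (3.04), Aplnr (2.64), Sorbs2 (2.47), Olfml2a (2.38), Fmod (2.16), Meox2 (2.03), Il1rl1 (1.73), Ptprb (1.69), Plvap (1.32) and Pecam1 (1.14). The endothelial list lay above it (median 1.14) with 2 of 17 genes called, beside collagens (0.49), fibroblasts (0.47), adipocytes (0.48) and tumour epithelial markers (0.05). Named genes below the sum were Alox5 (-3.0), Cwc22 (-2.94), Slpi (-1.63), Dok2 (-1.3), Itgb2 (-1.28) and Irf1 (-0.72), and no Gene Ontology term passed among genes below it (smallest adjusted p = 0.08). Among lists, neutrophils (-1.66), NF-kB targets (-1.0), hypoxia (-0.76), glycolysis (-0.58), clock (-0.45), Nrf2 targets (-0.4), interferon-gamma (-0.25), MHC class I (-0.25), the unfolded protein response (-0.19), fatty acid synthesis (-0.19) and oxidative phosphorylation (-0.11) were also below it. The interferon-gamma departure rests mainly on control 2 (level -0.55, against 0.099 and -0.092 in controls 1 and 3). Adjusted p was 0.15 to 0.6 with an estimated correlation for the 16 lists, and fry called only the clock (0.02) and endothelial cells (0.033).

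Among 100 regroupings of the 12 libraries that kept group sizes, only the real grouping, 1 of 100, gave as many as 34 interaction genes, with 1 as the highest other. For averaged curcumin 885 stood beside a highest other of 60, and for averaged swimming 277 beside 99. These draws break up every group at once, so they test neither the interaction nor an averaged effect by itself. They also treat the 12 libraries as exchangeable. The combination libraries varied less than the others (biological coefficient of variation 6.43% against 12% to 23.5%). Splitting such close libraries can widen the spread and lower the counts. The draws therefore cannot tell a treatment effect from that closeness. The interaction count was 0 with the combination libraries summed and 33 with control 2 left out as well, with 5 of the reported 34 among them, and the cause was not tested. The endothelial shift, 17 of 17 genes with adjusted p = 0.26 with an estimated correlation, stays open as a response to the combined treatment, because vessel content of the pieces taken was not measured apart from these genes.

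For pairs of groups, 10 splits are too few for a share under 0.05. The real counts and highest others were 663 and 0 for the combination against control, 116 and 0 against curcumin, 908 and 0 against swimming, and 243 and 0 for swimming against curcumin, with 1 of 10 splits as large in each. In the comparisons with the combination, a highest other of 0 could also come from splitting its close libraries. For swimming against control 42 stood beside a highest other of 298, with 2 of 10 as large. That split put control 1, control 3 and swimming 2 against control 2, swimming 1 and swimming 3, so it points to a structure of the samples other than the groups. For curcumin against control the real count was 0, so 10 of 10 were as large, and the highest other was 29.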

How the results depend on the processing

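Values follow a fixed order. It is curcumin versus tumour control, swimming versus tumour control, combination versus tumour control, combination versus curcumin alone, combination versus swimming alone, interaction of curcumin and swimming, curcumin averaged over swimming, swimming averaged over curcumin, and difference of response between curcumin and swimming. The reported counts were 0, 42, 663, 116, 908, 34, 885, 277 and 243. Scaling by RLE gave 0, 40, 627, 120, 905, 34, 893, 285 and 233, and no named gene or list that was called became called in the opposite direction under the settings run for it. Requiring a mean count of 50 moved little, and without a filter curcumin against control gave 2. DESeq2 gave more in all: 76, 310, 1628, 686, 1842, 210, 1971, 929 and 1016. A fit of only the groups compared gave 0 for curcumin, 0 for swimming, 132 for the combination, 2121, 2707 and, for swimming against curcumin, 659; it was not possible for the interaction and averaged effects. Testing against a 1.5-fold change left 0, 0, 3, 1, 6, 0, 2, 1 and 1. With a replicate block the counts were 1, 4, 220, 28, 496, 11, 337, 52 and 57. The replicate block is not a design of the study: of 18 pairs with the same number the median correlation was 0.011, and 5 of 12 libraries correlated best with their own number, so the numbers do not pair samples. Settings added after the results were seen moved more. Summing the combination libraries gave 0, 3, 0, 0, 0, 0, 1, 0 and 10, and leaving out control 2 as well gave 0, 156, 1, 0, 65, 33, 9, 26 and 650. Summing leaves 1 sample in the combination group, and its fitted changes stay near the reported ones by construction. A weight per group in limma voom gave 0, 0, 391, 1891, 2729, 39, 1400, 250 and 875. Leaving out each library gave 0 to 8, 0 to 603, 4 to 2182, 3 to 715, 31 to 2697, 0 to 455, 17 to 2595, 6 to 976 and 9 to 1537. The cause of these shifts was not tested by these settings. Of 252 calls at named genes, RLE ended 7, no filter 23, the replicate block 110, summing 251 and group weights 50. Grem1 over averaged curcumin kept its call under each alternative run for named genes, which left out the 1.5-fold test and, for averaged effects, the fit of only the groups compared. Of 135 list calls, an estimated correlation ended 135, fry 114 and summing 10. With totals of 15069348 to 17278826 counts, 3 counts correspond to 0.174 to 0.199 CPM, so depth limits what can be said of genes below that level.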

Other observations

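Further lists of tumour biology gave no shift past camera in any comparison. Genes of p53 targets had medians from -0.19 to 0.11 (lowest camera adjusted p = 0.405), with at most 3 called in a comparison. Apoptosis regulators ran from -0.03 to 0.09 (0.431, at most 3 called), among them Bcl2l11, which fell under averaged curcumin (-0.62, adjusted p = 0.014). The angiogenesis list of ligands and regulators ran from -0.12 to 0.24 (0.117, at most 2 called), unlike the endothelial list. Fatty acid oxidation and PPAR targets ran from -0.14 to 0.09 (0.105, at most 1 called). T cells ran from -0.66 to 0.35 (0.0565, 0 called) and immune checkpoints from -0.54 to 0.18 (0.0588, at most 2 called). Nerve and Schwann cell genes ran from -0.08 to 0.42 (0.0593, 0 called). Lists with under 5 tested genes were only described: B and plasma cells (4 genes, -0.75 to 0.23), erythroid cells (4, -1.62 to 1.53, at most 2 called), mammary epithelium (3, -0.09 to 0.53) and keratinocytes (2, -0.35 to 0.61). No Gene Ontology term passed among genes called lower in combination against control (smallest adjusted p = 0.33) or under averaged curcumin (0.27), or among those called higher in combination against curcumin (1) or in swimming against curcumin (0.81).

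Spread in the combination group was weighed with tests chosen after the result was seen, apart from the test of its spread, to which a control with other groups left out was added afterwards. The combination libraries differed little from each other, with a biological coefficient of variation of 6.43% against 12% to 23.5% elsewhere. With limma voom and the spread of the 9 other libraries, 278 genes were called against 731 with all 12; this met the prediction as written, but leaving out curcumin's spread instead gave 279, swimming's 480 and control's 1295, so the fall could not be assigned to the combination libraries. The median SD of 156 cell type markers was 0.11 in the combination libraries against 0.56 in control, 0.3 in curcumin and 0.5 in swimming, which could reflect repeats of a single tumour or pool. Count noise alone was too small to account for the differences between them, with chi-square per degree of freedom from 3.67 to 7.66, which argues against plain resequencing of a single preparation. Whether they came from separate animals stays open, and with it the meaning of every p-value that uses this group or the shared spread. All 9 comparisons were fitted with a spread shared over the 12 libraries. With the spread of the 9 other libraries, limma voom called 1 gene against 39 in swimming versus control. It called 37 against 168 in swimming against curcumin and 0 against 24 for the interaction. No other group's spread was left out for these comparisons, so these falls could not be assigned either.

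Control 2 was weighed with tests written before they were run, but an endothelial criterion was added after the result was seen. Its median position between the other controls (0) and swimming (1) was 0.89 over 600 genes, beside 0.98, 0.57 and 0.72 for held-out swimming libraries, which met the prediction as written for a mislabelled swimming tumour. Its endothelial level of 0.439 lay outside the swimming range of -0.852 to -0.212, which argues against that, so the tables cannot tell. Less skeletal muscle in the piece might lower genes mainly, and 73.7% of the genes 2-fold apart were lower (837 of 1136), between the bounds of 60 and 80 set beforehand. What sets the library apart stays open.

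Clock genes after swimming were weighed with a glucocorticoid test written beforehand and a phase test written after the result was seen. A margin was also added to the phase test afterwards. Glucocorticoid targets had a median of 0.48 after swimming (7 of 8 tested, 0 called), with Klf9 at 0.96, Mt1 at 0.89, Tsc22d3 at 0.82, Zbtb16 at 0.48 ± 0.58, Sgk1 at 0.45, Fkbp5 at 0.23 and Cebpd at -0.01. For these, fry, a rotation test on the fit of all 12 libraries and not an exact test, gave an unadjusted p of 0.0057, so a stress hormone response could contribute. The median was 0.24 in the combination against control, 0.44 against curcumin and -0.47 against swimming, with 0.19, 0.032 and 0.04 as unadjusted p from fry, and -0.13 (0.27) for curcumin alone. The 5 clock output genes had a median of 0.19, under the bound of 0.2 as written. The median lay within a margin of 0.12 around that bound, the SD of the 5 changes over the root of their number. The changes were 0.55 for Nr1d1, 0.26 for Dbp, 0.19 for Nr1d2, -0.04 for Per3 and -0.1 for Tef. A phase shift was predicted to give a median of at least 0.4 with Arntl lower, and neither was met, with Arntl at 0.16 ± 0.18, within its standard error of 0. A shift in the hour of collection therefore stays open, since the labels give no time of collection.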
